A study of Hypholoma fasciculare and Trametes versicolor and Trametes versicolor
Hypholoma fasciculare with 9 samples.

How the data were processed

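RNA was measured by sequencing of poly(A)-selected libraries from beechwood blocks colonised by wood-decay fungi. Trametes versicolor is a white-rot fungus and Hypholoma fasciculare a cord-forming one. The labels describe 3 libraries of T. versicolor alone, 3 of H. fasciculare alone and 3 of both fungi together, taken 14 h after contact. The labels do not say whether replicates are separate microcosms, so p-values measure only the spread between these libraries, which may be technical.

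The authors deposited 1 table with whole-number read counts per feature, not normalized, and beside them FPKM values. The submitters' processing notes name cutadapt 1.2.1, HISAT2, HTSeq and edgeR, without the step each served. Settings, genome builds and annotation are not given in the sources used here. Whether reads that fit both genomes were dropped, and whether counting used strand, is not given either. The table lists 14296 features whose ID starts with T_ and 17911 whose ID starts with H_. The T_ features were taken as T. versicolor because they hold 99.99% of the reads of the libraries labelled T. versicolor alone. Taking the H_ features as H. fasciculare rests on the ID prefix and on there being no other fungus in the labels, and was not tested on libraries of H. fasciculare alone. The table pairs no ID with a gene name, a description or a position, and no annotation was used here. The 28 gene lists fixed for this tissue (wood-degrading enzymes, peroxidases, cytochromes P450, stress proteins and others) were therefore not applied, and no coordinates are printed.

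The table has 9 count columns. Column names with T. versicolor and interaction, or T. versicolor and self, matched the interaction and T. versicolor control labels, replicate number included, and these 6 columns were used. The other 3 count columns are named as H. fasciculare in interaction, whereas the samples left over are labelled H. fasciculare alone. They can be read as H. fasciculare alone under another name or as further counts from the interaction, and nothing used here decides between these. They were not used, and the comparison of H. fasciculare features between interaction and control was not run. For the same reason, H. fasciculare reads counted on T. versicolor features were not measured.

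The deposited FPKM values served only to recover each feature's length from the ratio of count to FPKM and the column total, which agreed between libraries to a relative difference of 6.2e-15. A length was obtained for the 15194 features with a read in these 6 libraries.

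T. versicolor features were tested with edgeR 4.0.16 (R 4.3.3). Library size was the sum over T. versicolor features, because the interaction libraries mix 2 fungi. Filtering used filterByExpr with its default minimums, scaling used TMM, and the quasi-likelihood F test was robust. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM is the count scaled by the T. versicolor reads of the library, except where all reads are named as the total. Shares of reads were compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3. Intervals of shares are 95% Wilson intervals; they and limits from 3 counts cover counting error only, since no molecular identifiers are described for these reads.

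Design, alternatives and the rule for named features were set before the data were examined, except where stated. With IDs not paired with names, no more than 2 T. versicolor IDs that rose and 2 that fell are printed. The rule names the 2 features that rose and the 2 that fell most, among those with adjusted p under 0.05, no overlap between the 3 and 3 libraries and a mean of 20 CPM or more in the higher group. Its condition on reads from the other fungus was not applied, since these were not measured. A class of 11 abundant features, those with 200 reads or more in all 6 libraries, was defined after seeing the data. The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors in edgeR, no composition factor, both fungi in the library size, no filter, a filter of 5 CPM in 3 libraries, a replicate block, a fold threshold of 1.5, thinning to the smallest library, and leaving out each library. Alternatives added later were the fit without the 11 abundant features and TMMwsp scaling. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work.

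The edgeR fit was tested on simulated data with the real means and library sizes, for 14296 features of which 144 passed the filter. Every feature, the 11 abundant ones included, was given the common dispersion of the real fit (0.499), called the fitted dispersion below. Dispersions of single features were not used, and simulated rises and falls were equal in number. In the real data 83 passed, so the simulated counts differed from the real ones in this respect. The rates below hold for the simulated counts only. They were not measured under the scaling shifts or the missing reads seen in the real libraries. Of 25 tested features changed 4-fold, 7 were recovered. Of 43 changed 16-fold, 42 were recovered. Of 76 unchanged ones, 0 were called. At a low simulated dispersion, 197 features passed; 43 of 46 and 95 of 95 were recovered, and 5 of 56 unchanged ones were called.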

Results

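Transcripts were sequenced from beechwood blocks holding T. versicolor alone (control, n = 3 libraries) or T. versicolor in contact with H. fasciculare for 14 h (interaction, n = 3 libraries). The question was how gene expression of T. versicolor differs when it meets the mycelium of H. fasciculare. The control libraries held 5794424, 5665121 and 7389576 counted reads, and the interaction libraries 3889449, 3515400 and 4472646. The libraries of H. fasciculare alone were not analysed here.

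Nearly all reads fell on 11 short T. versicolor features, 150 to 624 bases long. These took 99.6% ± 0.0755 (SD, n = 3) of T. versicolor reads in the controls and 99.8% ± 0.209 (SD, n = 3) in the interaction. The most abundant in the controls, of 162 bases, held 38.5% ± 2.66 of T. versicolor reads in the controls and 22.2% ± 0.688 in the interaction (SD, n = 3 each). The most abundant in the interaction, of 500 bases, held 34.9% ± 1.12 in the controls and 35.9% ± 2.50 in the interaction (SD, n = 3 each). The class was defined after the counts were seen, and what these features encode is not given in the sources used here. By contrast, the 941 other T. versicolor features with 20 reads or more in all had a median length of 2641 bases.

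The depth outside these 11 features was small. It came to 16997, 20253 and 32794 reads in control replicates 1, 2 and 3, spread over 2448, 3172 and 9575 features. In interaction replicates 1, 2 and 3 it came to 3328, 15496 and 3354 reads over 1167, 2816 and 1469 features. As a share of T. versicolor reads this was 0.365% ± 0.0755 (SD, n = 3) in the controls and 0.201% ± 0.209 (SD, n = 3) in the interaction, a difference that the exact permutation test did not separate from the spread between libraries (p = 0.3, two-sided; 0.1 is the smallest it can give). By counting error alone, a feature with no read could still have been present up to a limit. That limit was 0.0894% or 0.0901% of the reads outside the 11 features in interaction replicates 3 and 1, and 0.0194% in replicate 2. Features with 10 reads or more in all 3 controls numbered 62 of 14285, and 1356 reached 10 reads in at least 1 control. The 62 compare with 0.719 if the libraries were independent and all features equally likely to reach 10 reads. Any spread in level between features gives an excess over that value, so it does not measure agreement between replicates.

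**Figure D1:**
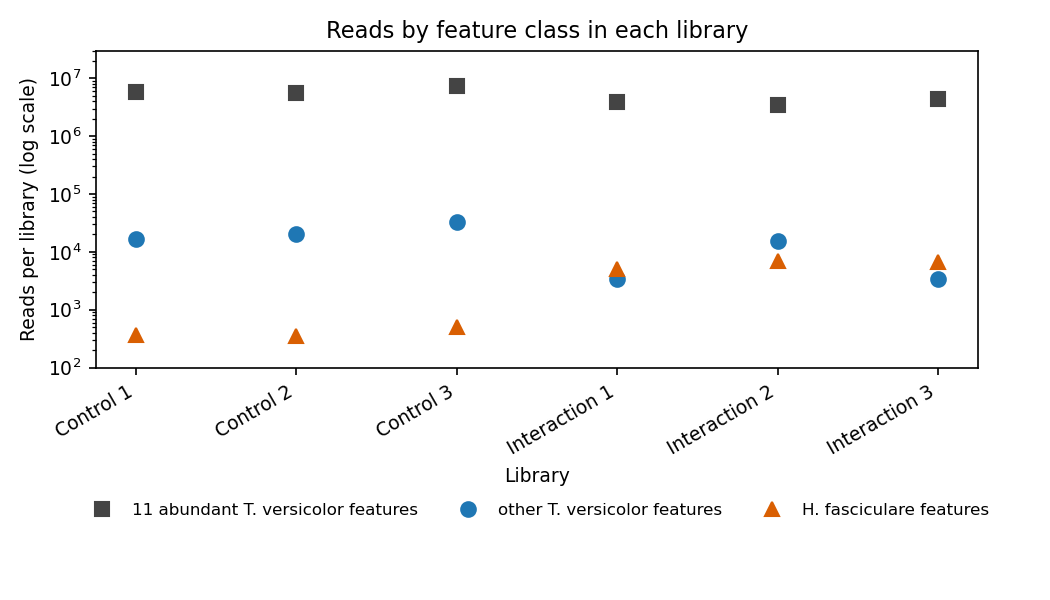
Reads per library (log axis) on the 11 abundant T. versicolor features (squares), on all other T. versicolor features (circles) and on H. fasciculare features (triangles), 1 point per library. H. fasciculare reads were 356 to 500 in the controls and 5018 to 6920 in the interaction, while other T. versicolor reads were lowest in interaction replicates 1 and 3.

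Features taken as H. fasciculare, from their ID prefix, had more reads in all 3 interaction libraries than in any T. versicolor control. They held 5018, 6920 and 6764 reads in interaction replicates 1, 2 and 3, against 364, 356 and 500 in the T. versicolor controls, which give the background. This was 0.159% ± 0.0346 of all reads in the interaction and 0.00644% ± 0.000279 in the controls (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest this design allows; higher in 3 of 3 libraries). Of the reads outside the 11 abundant features, H. fasciculare held 60.1% (95% Wilson interval 59.1 to 61.2), 30.9% (30.3 to 31.5) and 66.9% (65.9 to 67.8) in interaction replicates 1, 2 and 3. In the 3 controls it held 1.78% on average and 2.10% at most.

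Single H. fasciculare features were thinly covered. In the interaction, 26 had 10 reads or more in all 3 libraries, and 3 of these had no read in any control. The most abundant by mean share, named after their values were seen, were H_gene_8265 (1424 bases), with 341, 49 and 295 reads, and H_gene_10211 (1479 bases), with 204, 106 and 228 reads. In the controls these had 0, 8 and 29 reads and 6, 4 and 11 reads. Of 250 H. fasciculare features at a mean of 1 CPM of all reads or more in the interaction, 12 had a control mean of 10% or more of that level, and 9 features reached 1 CPM in the controls themselves. Whether H. fasciculare features changed on contact was not analysed here.

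Among T. versicolor features, more fell than rose in the interaction when levels were taken against the whole T. versicolor library, and this balance depended on the scaling. Of 83 features deep enough to test, 6 rose and 26 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The 11 abundant features gave 3 of the rises and 3 of the falls, and the other features 3 rises and 23 falls. Outside the 11, 62 features had 10 reads or more in all 3 controls and 5 in all 3 interaction libraries. The low-count filter thus gave falls more chance than rises of being tested. How far this set the balance was not tested. The median log2 fold change over all 83 was -1.54. With DESeq2 size factors in the same edgeR fit, the median was -0.28, and 13 features rose and 7 fell. With the 11 abundant features left out before scaling, a choice made after seeing the data, the median was -0.03, and 4 of 88 tested features rose and 1 fell. Each fit without 1 library was filtered anew and tested other features. Such fits called 3 of 174, 2 of 206 and 0 of 247 features without control replicates 1, 2 and 3 (with 33 at an unadjusted edgeR p under 0.05 in the last), and 3 of 270, 8 of 291 and 8 of 271 without interaction replicates 1, 2 and 3.

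**Figure D2:**
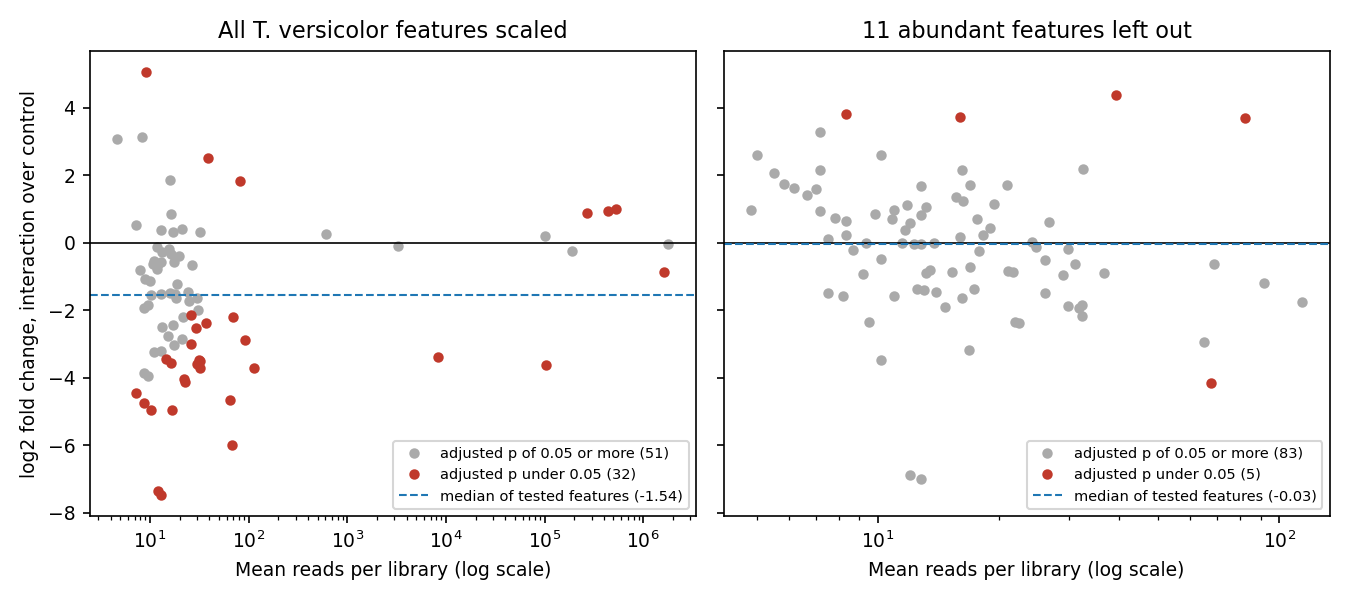
Log2 fold change of each tested T. versicolor feature, interaction over control, against its mean reads per library (log axis), with 3 libraries per group. Left, all T. versicolor features scaled together, with 32 called features in red and a median of -1.54 (dashed); right, the 11 abundant features left out, with 5 called features and a median of -0.03.

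T_gene_8201 (2314 bases) rose. It had 7.53 ± 3.36 CPM in the controls and 29.1 ± 1.15 CPM in the interaction (SD, n = 3 each), from 27, 38 and 83 reads and 113, 98 and 135 reads. Its log2 fold change was 1.82 ± 0.63 (SE; edgeR adjusted p = 0.0344), against the median of -1.54 over all tested features, and 3.69 ± 0.72 with the 11 abundant features left out (edgeR adjusted p = 0.00616). It was not called with TMMwsp scaling (edgeR adjusted p = 0.0572), against a fold threshold of 1.5 (edgeR adjusted p = 0.0598) or without a filter (edgeR adjusted p = 0.571). Nor was it called with the replicate block (edgeR adjusted p = 0.0849). How many of its interaction reads came from H. fasciculare was not measured here. T_gene_14113, an abundant feature of 282 bases, rose from 72087 ± 2933 to 157784 ± 37641 CPM (SD, n = 3 each), a log2 fold change of 1.01 ± 0.21 (SE; edgeR adjusted p = 0.00435). This value was the lowest of its range over 17 alternatives, 1.01 to 2.74, with 2.60 under DESeq2 size factors. It was not called with TMMwsp scaling (edgeR adjusted p = 0.0572) or without a filter (edgeR adjusted p = 0.571). Its CPM is a share of T. versicolor reads and is tied to the shares of the other abundant features.

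T_gene_555 (1268 bases) fell from 21.1 ± 4.89 to 0.299 ± 0.517 CPM (SD, n = 3 each). It had 90, 130 and 183 reads in the controls and 0, 0 and 4 in the interaction. Its fitted log2 fold change was -6.01 ± 1.08 (SE; edgeR adjusted p = 0.00144), and -4.16 ± 1.16 with the 11 abundant features left out (edgeR adjusted p = 0.0489). It was not called with TMMwsp scaling (edgeR adjusted p = 0.0572), nor with DESeq2 size factors once the 11 features were left out (edgeR adjusted p = 0.0840). T_gene_3908 (15598 bases) fell from 34.3 ± 5.39 to 2.66 ± 1.63 CPM (SD, n = 3 each), a log2 fold change of -3.71 ± 0.73 (SE; edgeR adjusted p = 0.00289). With the 11 abundant features left out its log2 fold change was -1.76 ± 0.83 (SE; edgeR adjusted p = 0.244), which no longer passed. Nor did it pass with DESeq2 size factors, TMMwsp scaling, thinning or no filter (edgeR adjusted p = 0.106, 0.231, 0.191 and 0.571). All 4 features kept their direction in each alternative that tested them, 17 for T_gene_14113 and 20 for each of the others. They were picked from these same libraries for large changes without overlap, so a kept direction adds little.

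**Figure D3:**
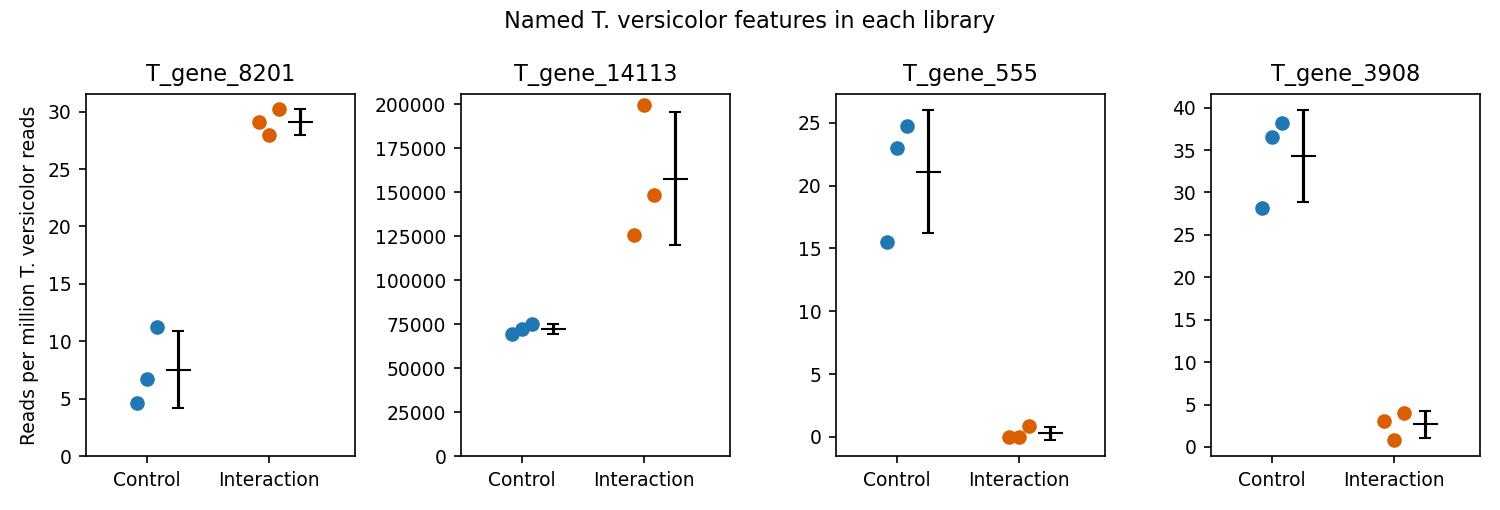
CPM within T. versicolor reads in each control and interaction library for the 4 named features, 1 point per library, with the group mean and SD (n = 3) beside the points. The 3 interaction values lie above the 3 control values for T_gene_8201 and T_gene_14113, and below them for T_gene_555 and T_gene_3908, which the rule for naming them required.

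The 11 abundant features did not move alike. T_gene_14113 and 2 further features rose, 3 fell and 5 did not pass the test when all T. versicolor reads set the scale. The 3 that rose had log2 fold changes of 0.87 to 1.01, and 2.48 to 2.60 under DESeq2 size factors. For 2 of the falls they were -3.62 and -3.39, and -2.17 and -1.93 under DESeq2 size factors. The feature of 162 bases had -0.87 ± 0.19 (SE; edgeR adjusted p = 0.00494), but 0.72, no longer past the threshold, under DESeq2 size factors. With those size factors 7 of the 11 rose and 2 fell. The shares of the 11 are tied to each other, since together they took 99.6% of T. versicolor reads in the controls and 99.8% in the interaction. A lower share of 1 therefore raises the shares of others, and the feature of 162 bases went from 38.5% to 22.2%. How far this made the 3 rises was not tested. How many reads on these features came from H. fasciculare in the interaction libraries was not measured here.

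Leaving out single libraries changed these counts and calls. edgeR with TMM called 32 of 83 features with all 6 libraries. Filtered anew without 1 library, it tested 124 to 281 features. It called 14, 0 and 10 without control replicates 1, 2 and 3 (with 23 at an unadjusted p under 0.05 where it called 0), and 8, 26 and 9 without interaction replicates 1, 2 and 3. Without interaction replicate 2, 18 rose and 8 fell. DESeq2, run without the low-count filter, called 0 of 11216 features, with 18 at an unadjusted p under 0.05. P-values spread evenly would put a share of 0.05 there, and 18 is far fewer. Its 0 calls therefore say little about the calls of edgeR on 83 filtered features. DESeq2 also gave the highest adjusted p of each named feature. T_gene_8201, T_gene_14113, T_gene_555 and T_gene_3908 all missed the threshold without control replicate 2, with edgeR adjusted p of 0.204, 0.204, 0.204 and 0.450. Their log2 fold changes were then 3.30, 2.47, -4.31 and -1.97, so the rises were larger and the falls smaller than with all 6 libraries. DESeq2 size factors in edgeR with all 6 libraries gave similar values, 3.51, 2.60, -4.30 and -1.96. Each fit without 1 library was also scaled anew, so such shifts cannot be laid to the library left out alone. The named features missed the threshold too without interaction replicate 1, with edgeR adjusted p of 0.0948, 0.198, 0.0679 and 0.347. Their log2 fold changes were then 3.21, 2.36, -4.03 and -2.08. Without interaction replicate 2 the log2 fold changes were 3.73, 2.74, -3.64 and -1.47, and T_gene_3908 missed the threshold (edgeR adjusted p = 0.135). Without interaction replicate 3 they were 2.45, 1.52, -9.83 and -3.28, and T_gene_14113 missed it (edgeR adjusted p = 0.358). Without control replicate 3 that of T_gene_8201 was 2.41. Over all alternatives, from edgeR, limma-voom and DESeq2, the adjusted p ranged from 2.9e-09 to 1.00 for T_gene_8201, from 2.9e-21 to 1.00 for T_gene_14113, from 8.9e-07 to 1.00 for T_gene_555 and from 6.1e-07 to 1.00 for T_gene_3908.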

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

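The fits without the 11 abundant features, TMMwsp scaling, the H. fasciculare share without those features and the count of other splits were chosen after the results were seen. Against 6 rises and 26 falls by edgeR with TMM (32 of 83 features), DESeq2 without the low-count filter called 0 of 11216 (18 at unadjusted p under 0.05). DESeq2 size factors in edgeR gave 13 rises and 7 falls (20 in all). No filter gave 0 rises and 2 falls (2 of 11217). A 5 CPM filter gave 9 rises and 13 falls of 33, thinning 7 and 9 (16 of 50), and a fold threshold of 1.5 gave 3 and 19. Leaving out the 11 abundant features gave 4 rises and 1 fall (5 of 88); with size factors 3 and 0 (3 in all), and with the replicate block 3 and 1 (4 in all). TMMwsp gave 4 and 3 (7 in all). Limma-voom, no composition factor and both fungi in the library size stayed within 1.5 times of each count. The last of these could hardly move a count. H. fasciculare held only 0.159% of all reads in the interaction and 0.00644% in the controls. That setting therefore does not test the mixing of the fungi, though the counts of alternatives given for the named features include it. Leaving out 1 library gave 0 to 26 calls by edgeR (0 without control replicate 2, with 23 at unadjusted p under 0.05), 0 to 18 rises and 0 to 9 falls. The causes were not tested. The 10 splits of the 6 libraries are too few for a share under 0.05; 1 split, the real one, gave 32 calls, and the highest other gave 0.

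The replicate numbers gave no sign of pairing (same-number correlations of deviations 0.10, -0.01 and -0.02, against -0.09 to 0.09 between different numbers). Features were often missing between libraries of a group, so this check could miss a pairing, and the labels do not settle it. With the replicate block 22 features were called, 4 rises and 18 falls, all among the 32; T_gene_8201 was not called (log2 fold change 1.94, adjusted p = 0.0849; range over its alternatives 2.9e-09 to 1.00). T_gene_8201, T_gene_14113, T_gene_555 and T_gene_3908 kept their direction in every alternative that tested them, past the threshold in 13 of 20, 11 of 17, 15 of 20 and 9 of 20. Since the same libraries served to pick them, the kept direction adds little. The H. fasciculare share in the interaction, 0.159% of all reads, was 0.140% to 0.174% without 1 library, 52.6% without the 11 abundant features and 46% without the 50 most abundant of each fungus. Of 9 H. fasciculare features at 1 CPM in the controls, 1 reached 5 CPM. The fit of all 9 libraries, the alternative without features open to reads of the other fungus, the H. fasciculare comparisons and the gene lists were not run, for lack of matched columns or descriptions. The filter left 83 of the 11217 T. versicolor features with a read, and how far low counts or reads on different features in each library set this number was not separated. The simulation varied the dispersion and not the depth, and its rates hold for its own counts only. Among tested features changed 4-fold it recovered 7 of 25 at the fitted dispersion and 43 of 46 at a low one, where it also called 5 of 56 unchanged ones. Of those changed 16-fold it recovered 42 of 43 at the fitted dispersion.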

Other observations

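The tests of scaling, of the reads outside the 11 abundant features, of reads of the other fungus, of Poisson sampling and of thinning were chosen after the results were seen, and so were the features singled out in this part. A set of T. versicolor features was read in all 3 control libraries and in none of the 3 interaction libraries. Of the 62 features with 10 reads or more in all 3 controls, 7 had no read in any interaction library, while 44, 41 and 38 of the 62 had a read in interaction replicates 1, 2 and 3. Against a limit of 3 counts over the 3 interaction libraries, a feature of 4133 bases with 20, 35 and 22 control reads was at least 16.1-fold lower per T. versicolor read, and at least 8.13-fold lower per T. versicolor read outside the 11 abundant features. For each of the 7 the bounds were at least 9.02-fold and 4.54-fold. All these bounds cover counting error only. Missing reads went beyond that error: of features with 10 reads or more in interaction replicate 2, 81.2% and 78.8% had none in replicates 1 and 3. Poisson sampling gives 6.65% and 6.53%, so a true difference could be smaller than its bound. The bounds per read outside the 11 features rest on interaction replicate 2, without which they were at least 2.45-fold for the feature of 4133 bases and at least 1.37-fold for each of the 7. The bounds per T. versicolor read were lowest without interaction replicate 3, at 10.1-fold and 5.62-fold. In the other direction 5 features had 10 reads or more in all 3 interaction libraries, T_gene_8201 among them, and 0 of these lacked reads in all 3 controls. This cut was harder to reach in interaction replicates 1 and 3, with 3328 and 3354 reads outside the 11 features. A feature of 917 bases missed it, with 0, 0 and 2 control reads against 18, 9 and 26 in the interaction. By edgeR with TMM it was called as a rise, with a log2 fold change of 5.06 ± 1.49 (SE). These features were picked for their values, so no p-value is given.

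With the 11 abundant features left out, edgeR called 4 rises, T_gene_8201 and 3 others with log2 fold changes of 4.39 ± 0.84, 3.72 ± 0.85 and 3.80 ± 1.06 (SE; adjusted p = 0.00616, 0.0176 and 0.0489). The first of these 3, of 2965 bases, had 21, 12 and 15 reads in the controls and 41, 46 and 100 in the interaction. The second, of 3236 bases, had 6, 5 and 17 against 17, 20 and 31. The third, of 5079 bases, had 3, 1 and 8 against 4, 23 and 11, counts that overlap. How many of the interaction reads on these 3 came from H. fasciculare was not measured here. The call for T_gene_555 was the only fall. Without control replicate 3, edgeR called 0 features in this setting, with 33 at an unadjusted p under 0.05, and without control replicates 1 and 2 and interaction replicates 1, 2 and 3 it called 3, 2, 3, 8 and 8, each time among other tested features.

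Most called features fell by edgeR with TMM, 26 of 32. With DESeq2 size factors in edgeR 35.0% of called features fell, and 1 called feature fell once the 11 abundant features were left out, but both settings bring the median log2 fold change near 0 (-0.28 and -0.03), which by itself evens out rises and falls. Where the median stayed lower, 3 of 7 called features fell with TMMwsp scaling (median -0.85). Without interaction replicate 2, 8 of 26 fell with TMM (median -1.20, other features tested). Most still fell with limma-voom (34 of 42, median -2.08), the replicate block (18 of 22, -2.15) and no composition factor (20 of 26, -1.40). So did most with the 5 CPM filter (13 of 22, -1.19) and without control replicates 1 and 3 (9 of 14, -0.93, and 6 of 10, -0.87). The balance thus moved in some settings, and leaving out interaction replicate 2 also renewed the filter and the scaling. The choice of scaling and a lower share of reads outside the 11 features both stay open. So does the low-count filter. Outside the 11 features, 62 had 10 reads or more in all 3 controls and 5 in all 3 interaction libraries, so falls had more chance of being tested. Without a filter 0 features rose and 2 fell (median -1.75), too few calls to decide. H. fasciculare reads counted on the abundant features stay open too, and counts from H. fasciculare alone, not analysed here, would bear on them: an abundant feature of 156 bases had a share 6.51, 15.9 and 26.8 times lower than the control mean in interaction replicates 1, 2 and 3, and its factor over that of the reads outside the 11 was 1.53, 19.3 and 5.51, where dilution alone would give 1. A response of T. versicolor to contact, the difference the design names, is open and was not tested apart from these.

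Features with many reads in 1 library were often missing from another library of the same group. Of the 599 features with 10 reads or more in control replicate 1, 56.1% had no read in control replicate 2, where Poisson sampling at that depth gives 0.000164%. Over the 12 ordered pairs of libraries within groups the share exceeded the Poisson value by 13.2 to 74.6 percentage points, which argues against the drawing of reads at this depth as the cause. Few starting molecules read many times each could account for it: control replicate 3, thinned to the reads of control replicate 2, still had 2.52 times as many features with a read, and thinned to those of replicate 1, 3.01 times as many. Differences between the blocks themselves were not tested and stay open.

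Some H. fasciculare features had reads in all T. versicolor controls. H_gene_6079 (1848 bases) had 38, 42 and 52 control reads, 10.9% ± 0.796 of the H. fasciculare reads there, against 1.60% ± 0.405 in the interaction (SD, n = 3 each). In all, 31 H. fasciculare features had a read in each of the 3 controls, and 509 in at least 1. Carry-over from the interaction libraries was examined in 2 ways, neither of which gave a usable test, so no result of it is given.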
